A study of Mus musculus with 45 samples.

How the data were processed

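RNA was sequenced from the hippocampus of mice that carry floxed copies of Apoe, with or without Csf1r-Cre, a transgene that expresses Cre recombinase in microglia and other cells of the myeloid lineage, and with or without 5xFAD, a transgenic model of amyloid pathology whose transgenes are driven by the Thy1 promoter. The 45 libraries fall into 8 groups by genotype and age (4 or 12 months), taken from the sample titles. Per the labels' protocols, brains were microdissected into cortex, hippocampus and a thalamus and striatum part, RNA was extracted with a column kit, and libraries were sequenced as paired ends on Illumina instruments. The labels do not state sex. The labels number the samples within each group but do not say that each came from a separate animal, so p-values measure the spread between these samples. The titles of the 12-month 5xFAD samples name no Csf1r-Cre while their strain entry does; the titles were followed, and the series design lists such a group.

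The authors deposited 1 table of TPM values, transcript abundances scaled for gene length and library total, with 54532 genes, named by Ensembl identifier and symbol, and mm10 coordinates. Per the submitters' processing notes, STAR, featureCounts, edgeR and limma were used and the genome build was mm10; their versions and settings are not given in the sources used here, nor is the use of strand or of reads that map to several places. Every library's TPM summed to the same total. Of the 33023 genes above 0 in at least 1 sample, 100% had values that were whole numbers of reads in every sample, within a tolerance of 0.02, once a single length per gene was allowed for, and 14169 of these lengths matched the gene length listed in the table. Such a length can be found for nearly any gene above 0 in only 1 sample. All 22910 genes above 0 in at least 10 samples had whole reads too. These reads came to 13957863 to 20770008 per sample in genes, so 1 read on a gene of 1000 bases was worth 0.0573 to 0.0902 TPM. TPM were not turned into counts for any test. The symbol column repeats 105 symbols, and genes were joined by identifier.

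Expression was analysed as log2(TPM + 0.5) for the 18659 genes with a TPM of at least 0.5 in at least 3 samples. A log2 fold change on this scale understates the change of genes with low TPM. Each comparison was a contrast in a linear model with 1 mean per group over all 45 samples, fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes with a trend on mean expression), two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Adjusted p-values of genes come from this limma model. With no change at all, about 5% of the 18659 genes would have an unadjusted p under 0.05, so such counts are not calls. There were 13 comparisons: 5xFAD against its control at each age, with and without Csf1r-Cre; Csf1r-Cre against none at each age, with and without 5xFAD; the mean of those 4 Csf1r-Cre differences; the difference of the 5xFAD effect with Csf1r-Cre at each age; the difference of the 5xFAD effect between ages; and 12 against 4 months without 5xFAD. Apoe was compared with exact two-sided permutation tests on log2(TPM + 0.5), adjusted over the 4 comparisons.

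The groups, the model, the alternatives, 31 gene lists and the rule for named genes were fixed before the data were examined. The rule took Apoe in every comparison and App and Thy1 where 5xFAD was present, the 10 highest and 10 lowest log2 fold changes among called genes with a mean of at least 1 TPM in a compared group, leaving out predicted gene models and the sex-linked Xist, Tsix, Ddx3y, Eif2s3y, Kdm5d and Uty, and up to 4 members of each list with the smallest p; where no gene was called, it took the 5 smallest p. Genes named outside this rule are said to be so, and some genes that the rule takes are not reported here. Lists were tested with camera at a preset correlation between genes of 0.01, again with the correlation estimated from the data, and with fry, and adjusted over the lists within each comparison. Fry values are given for some lists only and are named as such. The reads of a gene and of a near-identical copy, such as a processed pseudogene, may be split between them, and values of such genes are uncertain.

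The code was tested on simulated data with the real genes' means and spreads, 18659 genes per run. Values were drawn independently for each gene and library, without correlation between genes or outlying libraries, so the rates need not hold for the real data. For 5xFAD against control at 12 months it recovered 45% of genes changed by 1 on the log2 scale and 87% of those changed by 2; for 5xFAD with Csf1r-Cre at 12 months these were 51% and 91%, for 5xFAD at 4 months 53% and 91%, and for Csf1r-Cre over all backgrounds 90% and 100%. Unchanged genes made up 9 of the 147, 9 of the 157, 9 of the 163 and 17 of the 234 genes called in these runs, or 6.12%, 5.73%, 5.52% and 7.26%, above the 5% aimed at. Alternatives were other pseudocounts, no filter, TPM divided by a median-of-ratios size factor per sample, a fit on the compared groups alone, sample weights, Xist level as a covariate, replicate number as a block, and leaving out each replicate; 2 more were added after the data were seen, both without the 2 libraries that correlate least with the rest. Figures were drawn with matplotlib.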

Results

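Hippocampal RNA was profiled in 8 groups of mice with floxed Apoe. At 4 months there were 8 control samples, 6 with Csf1r-Cre, 5 with 5xFAD and 4 with both. At 12 months there were 3, 7, 7 and 5. The design asks what the loss of Apoe from Csf1r-expressing cells, chiefly microglia, does in the hippocampus with and without amyloid pathology. Depth was 13957863 to 20770008 reads in genes per sample. A single gene, Gm23935, took 0.427% to 28.8% of a library's TPM. The closest pair of libraries correlated at 0.988, and none was counted as a duplicate. The 2 libraries that correlated least with the rest were 12-month Csf1r-Cre replicate 2, with a median correlation of 0.886 and 2987 TPM of hemoglobin transcripts, and 12-month control replicate 2, at 0.939.

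Apoe itself (ENSMUSG00000002985), the targeted gene, was expressed in every sample, between 1292 and 5434 TPM, and its total level did not pass the test in any comparison of Csf1r-Cre with none. At 4 months Apoe was 3328 ± 1093 TPM (SD, n = 6) with Csf1r-Cre and 3327 ± 730 TPM (SD, n = 8) without, with an exact permutation p of 0.936. At 12 months it was 3174 ± 931 TPM (SD, n = 7) against 3028 ± 380 TPM (SD, n = 3), with an exact permutation p of 1; this design could reach 0.00833. In 5xFAD samples it was 2860 ± 233 TPM (SD, n = 4) against 2824 ± 647 TPM (SD, n = 5) at 4 months, exact permutation p = 0.865, and 4001 ± 458 TPM (SD, n = 5) against 3979 ± 773 TPM (SD, n = 7) at 12 months, exact permutation p = 0.874. The adjusted p was 1 in all 4. The differences in mean log2(TPM + 0.5) were -0.018, -0.0022, 0.046 and 0.025 in this order, so at both ages without 5xFAD they were just below 0 while the mean TPM was not lower with Csf1r-Cre. With TPM divided by median-of-ratios size factors these log2 differences had the opposite sign, 0.14, 0.27, -0.0040 and -0.065, and none passed the test. Astrocytes also express Apoe, and a transcript that lacks the floxed part would still add to the gene's TPM, so the total level is a weak check of the genotype labels.

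**Figure D1:**
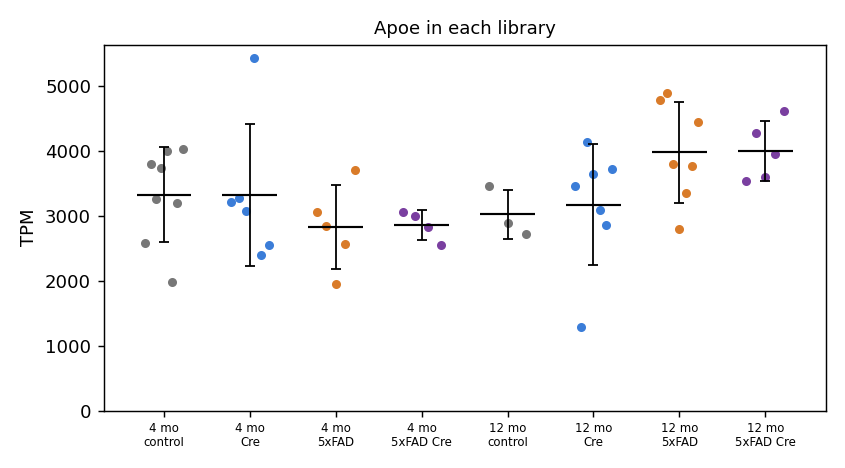
Apoe in each library, in TPM, by group; points are libraries, horizontal lines are means and error bars are 1 SD. The Csf1r-Cre groups overlap their controls at both ages, for example 3328 ± 1093 TPM against 3327 ± 730 TPM at 4 months.

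5xFAD against control at 4 months, without Csf1r-Cre, raised 2 genes, both of the microglial state seen around amyloid plaques. Cst7, a cystatin that inhibits cysteine proteases, was 7.37 ± 7.44 TPM (SD, n = 5) against 0.323 ± 0.351 TPM (SD, n = 8), a log2 fold change of 2.94 ± 0.45 (SE, adjusted p = 0.000746). Ccl6, a chemokine, was 44.6 ± 35.7 TPM against 4.96 ± 1.27 TPM, a log2 fold change of 2.70 ± 0.39 (SE, adjusted p = 0.00034). Of the 35 measured genes of the plaque-associated microglia list, 2 passed over all genes and 10 when adjusted over the list alone. The camera call of this list was lost, with adjusted p = 0.119 with an estimated correlation, and its fry adjusted p was 0.254. Members that did not pass included Clec7a, a pattern recognition receptor, at 4.69 ± 3.80 TPM against 0.581 ± 0.435 TPM. None of the 22 immediate early genes passed over all genes and 5 were lower when adjusted over the list alone (adjusted p = 0.68 with an estimated correlation). Npas4 was 0.496 ± 0.294 TPM against 3.93 ± 2.98 TPM and Arc 9.20 ± 1.93 TPM against 36.4 ± 25.4 TPM. Beside these, markers of thalamus lay at a median log2 fold change of -1.21, synapse genes at -0.70 with all 25 lower, markers of cortex at -0.71 with all 13 lower, of oligodendrocytes at -0.58 with all 16 lower, of endothelium at -0.53 and of mural cells and fibroblasts at -0.64. Each had a camera call and an adjusted p = 0.68 with an estimated correlation. Homeostatic microglia, interferon response, class I, complement, CA pyramidal cell and mitochondrial lists had upward camera calls, also with an adjusted p of 0.68 with an estimated correlation. Camera sets a list against the other genes, so such a call need not be a rise. Their median log2 fold changes were 0.08, 0.07, 0.04, 0.097, -0.07 and 0.03 in this order. The T cell list had an upward call too (adjusted p = 0.119 with an estimated correlation). The median of all genes moved by -0.23 between the groups, and to 0 with median-of-ratios scaling, which called 5 genes. A fit on these 2 groups alone called 0, where 1759 genes had an unadjusted p under 0.05 in the limma model. Without 4-month 5xFAD replicate 1 the count was 7, and without replicate 4 Cst7 averaged 4.15 TPM (adjusted p = 0.0207).

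With Csf1r-Cre in both groups at 4 months, 5xFAD raised 1 gene, again Ccl6, at 47.9 ± 38.9 TPM (SD, n = 4) against 4.86 ± 1.94 TPM (SD, n = 6), a log2 fold change of 2.78 ± 0.44 (SE, adjusted p = 0.00258). Cst7 was 9.08 ± 8.22 TPM against 0.737 ± 0.572 TPM (adjusted p = 0.0934) and Trem2, a lipid receptor of microglia, was 41.3 ± 19.9 TPM against 17.6 ± 2.77 TPM (adjusted p = 0.28). Over all genes, 1 of the 35 plaque-associated genes passed, and 10 when adjusted over the list alone (adjusted p = 0.223 with an estimated correlation). Of the 18 homeostatic microglia genes 0 passed over all genes in limma, and 5 were higher when adjusted over the list alone (adjusted p = 0.223 with an estimated correlation). Beside these, markers of oligodendrocytes lay lower in all 16 cases (median -0.72, adjusted p = 0.328 with an estimated correlation) and of striatum in all 14 (-1.26, adjusted p = 0.844 with an estimated correlation), and markers of dentate granule cells lay higher in 9 of 11 (0.72, adjusted p = 0.223 with an estimated correlation) and of blood in all 6 (0.63, adjusted p = 0.62 with an estimated correlation). In the limma model 959 genes had an unadjusted p under 0.05, close to the 5% of the 18659 genes tested that chance gives. The median of all genes moved by -0.10. The count became 0 without 5xFAD Csf1r-Cre replicate 1, 4 without its replicate 2, 5 without its replicate 3 and 2 without Csf1r-Cre replicate 4, all at 4 months. Ccl6 had an adjusted p of 0.123 and 0.0713 without 5xFAD Csf1r-Cre replicates 1 and 4. Median-of-ratios scaling called 3.

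At 12 months 5xFAD, without Csf1r-Cre, brought a broad rise of microglial, antigen presentation, complement and reactive astrocyte genes. It raised 306 genes and lowered 24. Cst7 reached 47.7 ± 11.8 TPM (SD, n = 7) against 1.01 ± 0.341 TPM (SD, n = 3), a log2 fold change of 4.98 ± 0.55 (SE, adjusted p = 1.93e-07). Itgax, the integrin CD11c, was 22.9 ± 3.86 TPM against 0.582 ± 0.697 TPM (log2 fold change 4.63, adjusted p = 1.59e-08). Clec7a was 28.4 ± 8.53 TPM against 1.04 ± 1.13 TPM (log2 fold change 4.49, adjusted p = 6.66e-07), and Spp1, osteopontin, was 95.3 ± 42.8 TPM against 7.43 ± 5.38 TPM (log2 fold change 3.73, adjusted p = 0.00235). Thy1, whose promoter drives the transgenes, rose from 880 ± 300 TPM to 1900 ± 372 TPM (log2 fold change 1.14, adjusted p = 0.0303), while mouse App was 518 ± 133 TPM against 552 ± 304 TPM (adjusted p = 1). Thy1 did not pass without control replicate 1 (adjusted p = 0.192) or 3 (0.0765), or without 5xFAD replicate 3 (0.0635), 5 (0.0507) or 6 (0.0594). The control mean was 0.434 TPM for Clec7a and 0.196 TPM for Itgax without control replicate 1, and 4.57 TPM for Spp1 without control replicate 2.

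By group at 12 months, 23 of the 35 plaque-associated microglia genes rose over all genes, 29 when adjusted over the list alone, and none fell (adjusted p = 0.00157 with an estimated correlation). Among 18 homeostatic microglia genes 5 rose, 14 when adjusted over the list alone (adjusted p = 0.0419 with an estimated correlation). Antigen presentation rose: 8 of 14 class I genes, 12 when adjusted over the list alone, with B2m, the light chain of class I molecules, at 626 ± 99.1 TPM against 222 ± 78.2 TPM, and 4 of 6 class II genes, 5 when adjusted over the list alone, with H2-Aa at 55.0 ± 30.5 TPM against 5.04 ± 6.36 TPM (both lists adjusted p = 0.011 with an estimated correlation). Of 13 complement genes 7 rose, 9 when adjusted over the list alone (adjusted p = 0.0162 with an estimated correlation), among them C1qa at 546 ± 144 TPM against 198 ± 31.2 TPM. Of 18 reactive astrocyte genes 6 rose, 10 when adjusted over the list alone (adjusted p = 0.0419 with an estimated correlation); Gfap, the astrocyte intermediate filament, was 1223 ± 526 TPM against 190 ± 109 TPM. Among 9 T cell markers 1 rose, Trac, the T cell receptor alpha constant chain, at 2.45 ± 1.64 TPM against 0.375 ± 0.392 TPM, and 4 when adjusted over the list alone (adjusted p = 0.0419 with an estimated correlation). The 12-month Csf1r-Cre samples without 5xFAD had a mean Trac no lower than this, and they are compared below with these same controls. The T cell list had a camera adjusted p of 0.103 without the 2 libraries that stand apart. Without control replicate 2 the adjusted p was 0.0608 for B2m, 0.0974 for H2-Aa and 0.372 for Trac, and without control replicate 3 the control mean was 1.47 TPM for H2-Aa and 0.172 TPM for Trac.

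Other lists lost their camera call. Interferon response genes rose in 7 of 27 cases, 19 when adjusted over the list alone (adjusted p = 0.0601 with an estimated correlation), lysosomal genes in 8 of 27, 11 when adjusted over the list alone (adjusted p = 0.0772 with an estimated correlation), and microglial genes near Alzheimer's disease risk loci in 6 of 20, 10 when adjusted over the list alone (adjusted p = 0.0772 with an estimated correlation). These lists did pass with fry, at an adjusted p of 0.0029, 0.00688 and 0.00565 in this order. Trem2 was 85.7 ± 23.2 TPM against 20.9 ± 5.52 TPM. Mitochondrial transcripts lay at a median log2 fold change of -0.51 (adjusted p = 0.0772 with an estimated correlation), and none of the 15 passed over all genes. Markers of striatum lay lower in all 14 cases, at a median log2 fold change of -1.69 (adjusted p = 0.266 with an estimated correlation), and immediate early genes in 17 of 22 (median -0.80, adjusted p = 0.322 with an estimated correlation). Markers of oligodendrocytes lay higher in all 16 cases (median 0.44, adjusted p = 0.677 with an estimated correlation) and of border macrophages in 9 of 10 (0.88, adjusted p = 0.407 with an estimated correlation). The fry adjusted p was 0.102 for mitochondrial transcripts, 0.264 for striatum, 0.331 for immediate early genes and for oligodendrocytes, and 0.105 for border macrophages. Lower genes included Kirrel2, an adhesion molecule, at 1.76 ± 0.770 TPM against 7.12 ± 2.65 TPM (log2 fold change -1.77, adjusted p = 0.000468). Of the 10 named lower genes, Kirrel2 alone kept an adjusted p under the threshold, 0.0176, without the 2 libraries that stand apart, and H2-Aa (0.0694), Cd52 (0.0884) and H2-Eb1 (0.199) lost theirs. That fit called 129 genes, the count was 80 without control replicate 2 alone and 575 without control replicate 3, and a fit on these 2 groups alone called 172. With median-of-ratios scaling 257 genes rose and 49 fell, so the share that rose went from 92.7% to 84%, and 229 genes were called in both scalings.

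**Figure D2:**
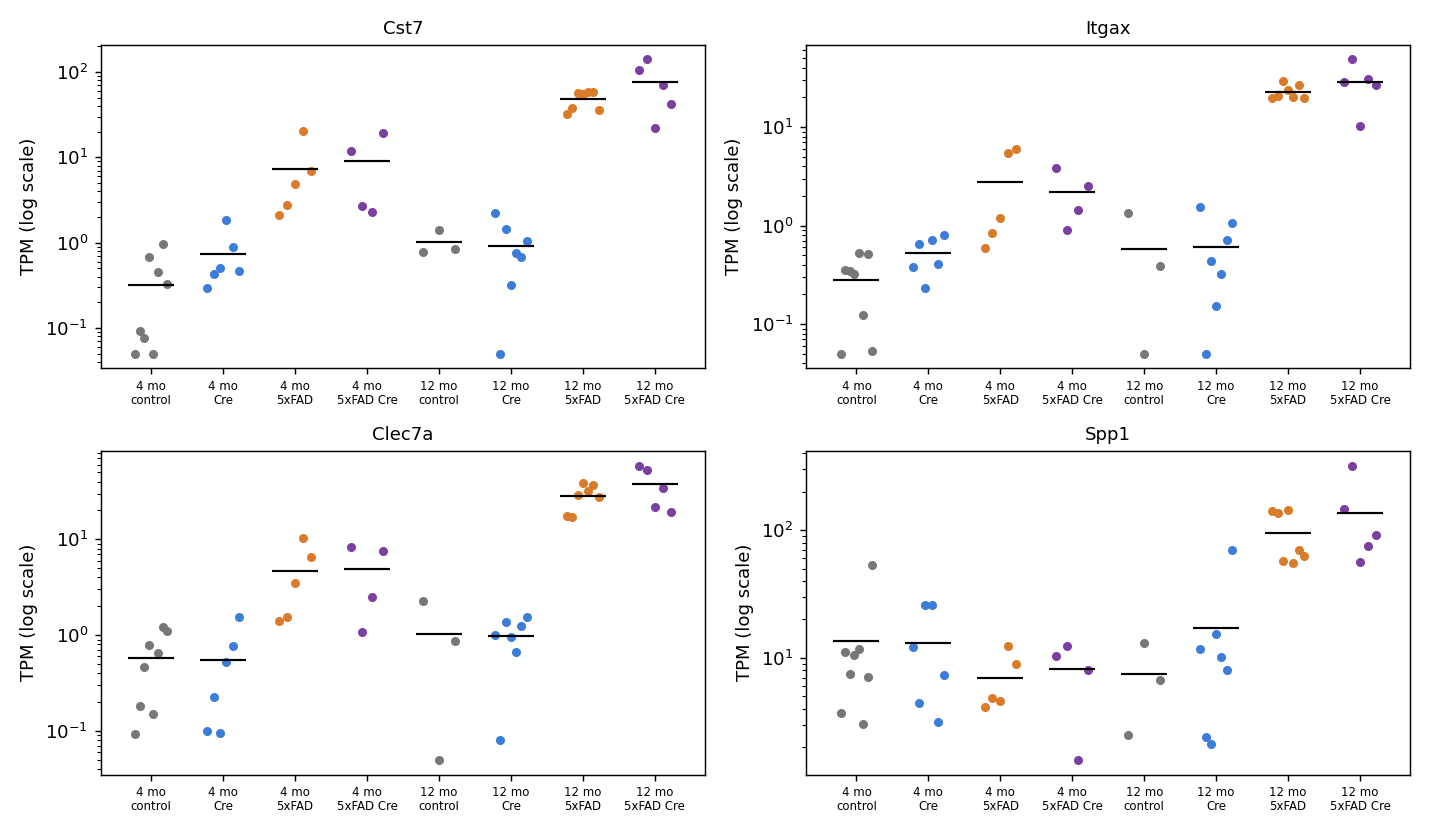
Cst7, Itgax, Clec7a and Spp1 in each library, in TPM on a log axis, by group; points are libraries, lines are means, and values under 0.05 TPM are drawn at 0.05. Cst7 averages 47.7 TPM in 12-month 5xFAD against 1.01 TPM in its control, and 7.37 TPM against 0.323 TPM at 4 months.

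Microglial, complement, class I and reactive astrocyte genes also rose with 5xFAD at 12 months where both groups carried Csf1r-Cre. Here 1056 genes rose and 68 fell. Cst7 was 76.1 ± 47.9 TPM (SD, n = 5) against 0.922 ± 0.733 TPM (SD, n = 7), a log2 fold change of 5.65 ± 0.47 (SE, adjusted p = 2.93e-11). Gpnmb, a glycoprotein of lipid-laden macrophages, was 61.8 ± 57.0 TPM against 3.57 ± 1.84 TPM (log2 fold change 3.64, adjusted p = 3.94e-08). Serpina3n, a protease inhibitor of reactive astrocytes, was 244 ± 260 TPM against 15.8 ± 8.28 TPM (log2 fold change 3.61, adjusted p = 2.03e-07). Without 5xFAD Csf1r-Cre replicate 2, Gpnmb averaged 38.1 TPM (adjusted p = 8.38e-07) and Serpina3n 129 TPM (adjusted p = 4.08e-06). Of the genes raised by 5xFAD without Csf1r-Cre, 232 were also raised here, where independent lists of these sizes would share 17.3. Of the 24 genes lowered there 1 was also among the 68 lowered here, where independent lists would share 0.0875. It was Gm11627 (log2 fold change -1.53, adjusted p = 0.0407, and -1.46, adjusted p = 0.00568), a predicted model outside the naming rule that was named after its values were seen. These comparisons share no library, and 0 genes moved in opposite directions.

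By group, 30 of the 35 plaque-associated microglia genes rose, 34 when adjusted over the list alone (adjusted p = 0.00496 with an estimated correlation), and all 18 homeostatic microglia genes rose by either count (adjusted p = 0.0148 with an estimated correlation), 14 of them with median-of-ratios scaling. Complement genes rose in 11 of 13 cases, 13 when adjusted over the list alone (adjusted p = 0.0145 with an estimated correlation), with C4b at 343 ± 157 TPM against 34.1 ± 17.8 TPM and C1qc at 479 ± 184 TPM against 116 ± 14.2 TPM. Class I genes rose in 13 of 14 cases by either count (adjusted p = 0.0206 with an estimated correlation), interferon response genes in 23 of 27, 26 when adjusted over the list alone (adjusted p = 0.0492 with an estimated correlation), and reactive astrocyte genes in 11 of 18, 15 when adjusted over the list alone (adjusted p = 0.0206 with an estimated correlation). Gfap was 1843 ± 897 TPM against 196 ± 106 TPM. Microglial genes near Alzheimer's disease risk loci rose in 14 of 20 cases, 18 when adjusted over the list alone (adjusted p = 0.0204 with an estimated correlation), with Trem2 at 122 ± 47.1 TPM against 22.2 ± 1.16 TPM. Lysosomal genes rose in 17 of 27 cases, 24 when adjusted over the list alone (adjusted p = 0.0736 with an estimated correlation). Lipid transport genes rose in 7 of 20, 13 when adjusted over the list alone (adjusted p = 0.356 with an estimated correlation); Abca1, a cholesterol exporter, was 16.7 ± 12.2 TPM against 3.54 ± 2.19 TPM. Class II genes rose in 3 of 6 cases, 4 when adjusted over the list alone (adjusted p = 0.331 with an estimated correlation). Thy1 rose from 745 ± 279 TPM to 2354 ± 813 TPM (log2 fold change 1.69, adjusted p = 7.96e-06).

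Lower genes included Tpd52l1, at 36.5 ± 10.9 TPM against 79.3 ± 14.9 TPM (log2 fold change -1.14, adjusted p = 0.000136), Hes5, a Notch target, at 4.74 ± 2.55 TPM against 9.95 ± 3.84 TPM (log2 fold change -1.08, adjusted p = 0.0454), and mt-Co3, a mitochondrial subunit of cytochrome oxidase, at 319 ± 155 TPM against 889 ± 606 TPM (adjusted p = 0.00591). The adjusted p of Hes5 was 0.0856 without the 2 libraries that stand apart, 0.0754, 0.0835, 0.0649 and 0.0911 without Csf1r-Cre replicates 1, 2, 4 and 7, and 0.145 and 0.208 without 5xFAD Csf1r-Cre replicates 1 and 2. Beside these, markers of choroid plexus lay at a median log2 fold change of -1.33 and of striatum at -1.34 (both adjusted p = 0.331 with an estimated correlation), of thalamus at -0.52 (adjusted p = 0.356 with an estimated correlation) and of blood at -0.49 (adjusted p = 0.357 with an estimated correlation). Markers of excitatory neurons lay at 1.06 (adjusted p = 0.356 with an estimated correlation) and synapse genes at 0.92 (adjusted p = 0.62 with an estimated correlation). The median of all genes moved by 0.27, and relative to it the plaque-associated list lay at 1.74. With median-of-ratios scaling 739 genes rose and 404 fell, so the share that rose went from 94% to 64.7%. The count was 3019 without Csf1r-Cre replicate 3, 707 without its replicate 2, and 532, 2692 and 692 without 5xFAD Csf1r-Cre replicates 2, 3 and 4, while a fit on these 2 groups alone called 275 and sample weights 3174.

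**Figure D3:**
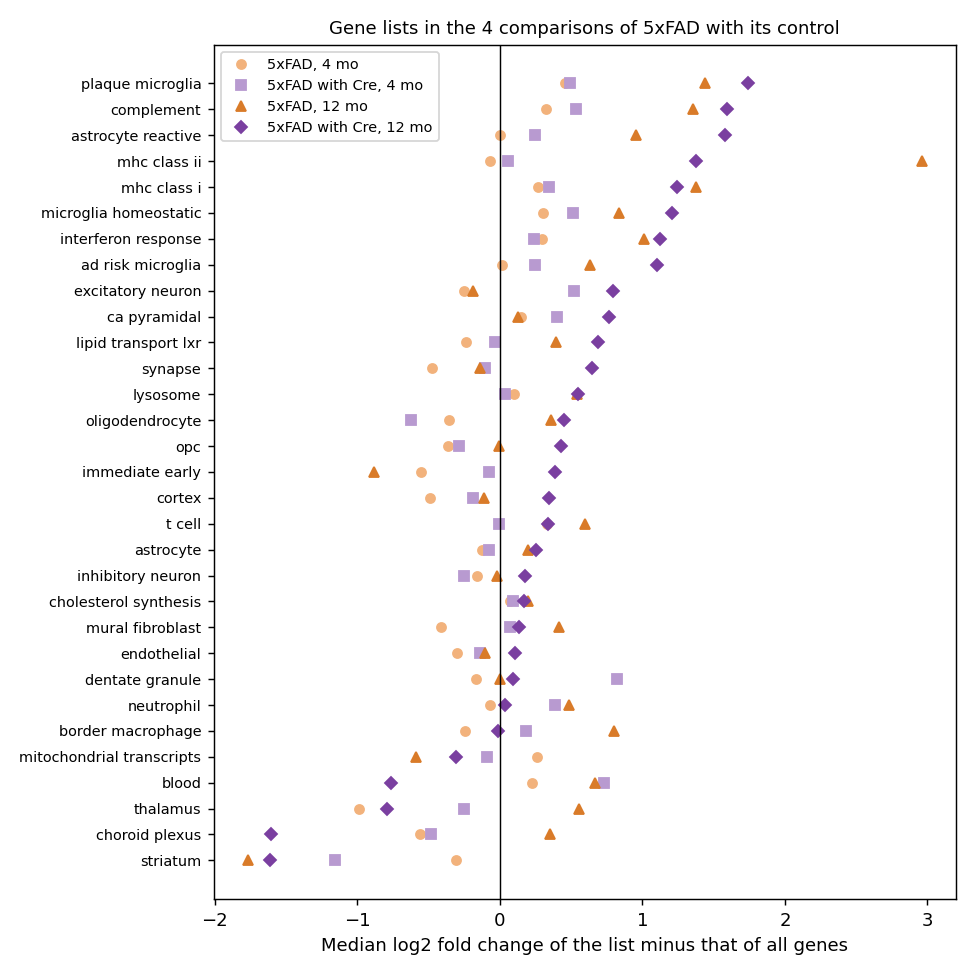
Median log2 fold change of each gene list minus that of all genes, for the 4 comparisons of 5xFAD with its control; each point is 1 list in 1 comparison. The plaque-associated microglia list lies at 1.44 at 12 months without Csf1r-Cre and 1.74 with it, and at 0.46 and 0.50 at 4 months.

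Whether the 5xFAD effect grew with age was tested directly over both Csf1r-Cre states. The effect was more positive at 12 than at 4 months for 787 genes and more negative for 15. Spp1 differed by 4.14 ± 0.68 on the log2 scale (SE, adjusted p = 0.000423), Itgax by 3.19 ± 0.41 (SE, adjusted p = 4.75e-06), Hpse, heparanase, by 2.96 ± 0.34 (SE, adjusted p = 4.96e-07) and Cd74, the class II invariant chain, by 3.32 ± 0.70 (SE, adjusted p = 0.00483). Of the 35 plaque-associated genes 25 differed, 33 when adjusted over the list alone (adjusted p = 0.0986 with an estimated correlation). Of 27 lysosomal genes 17 differed, 26 when adjusted over the list alone (adjusted p = 0.112 with an estimated correlation), and of 16 oligodendrocyte genes 12 differed, all 16 when adjusted over the list alone (adjusted p = 0.204 with an estimated correlation), with Opalin, a myelin membrane protein, at 1.22 ± 0.29 (SE, adjusted p = 0.012). Under median-of-ratios scaling Opalin lay at 0.79 with an adjusted p of 0.165, and 3 of the 16 passed. Markers of striatum lay at a median difference of -0.57, negative in all 14 cases (adjusted p = 0.399 with an estimated correlation), and mitochondrial transcripts at -0.19 (adjusted p = 0.0986 with an estimated correlation). The median of all genes differed by 0.34. With median-of-ratios scaling 475 genes passed, 380 of them positive, so that share went from 98.1% to 80%. The count was 1543 without the 2 libraries that stand apart, 448 and 1627 without 12-month 5xFAD Csf1r-Cre replicates 2 and 3, 1568 without 12-month Csf1r-Cre replicate 3, 462 without 4-month 5xFAD replicate 3 and 1215 without 4-month control replicate 6.

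Csf1r-Cre changed few genes, among them the proton pump gene Atp6v0c and several pseudogenes. Over all backgrounds 21 genes were higher and 5 lower. Atp6v0c (ENSMUSG00000024121, mm10 chromosome 17, 24163866 to 24169702), a subunit of the vacuolar proton pump, fell from 382 ± 61.3 TPM (SD, n = 23) to 186 ± 25.0 TPM (SD, n = 22), a log2 fold change of -1.02 ± 0.07 (SE, adjusted p = 1.32e-13). Its processed pseudogene Atp6v0c-ps2 (chromosome 6, 37806086 to 37806550) rose from 16.6 ± 10.3 TPM to 442 ± 58.2 TPM (log2 fold change 4.85, adjusted p = 2.54e-29). Rps2-ps10, a pseudogene of a ribosomal protein gene (chromosome 18, 61259008 to 61259972), rose from 2.13 ± 0.790 TPM to 394 ± 173 TPM (log2 fold change 6.94, adjusted p = 7.58e-19), and Hmga1b, a retained copy of Hmga1 (chromosome 11, 120762794 to 120764419), from 1.19 ± 3.03 TPM, with 15.0 TPM in 4-month control replicate 6, to 18.4 ± 6.95 TPM (log2 fold change 3.92, adjusted p = 3e-12). All 3 copies share sequence with their parent genes, so these values are uncertain. On chromosome 17 Prss41, H2-T10 and Ccr6 were higher and Gtpbp2, H2-T22, Rnps1 and Spsb3 lower; H2-T22 (adjusted p = 0.583) and Spsb3 (0.277) did not pass with median-of-ratios scaling, and Spsb3 (0.109) did not without the 2 libraries that stand apart. Beside these, markers of striatum lay lower in all 14 cases (median -0.64, adjusted p = 0.878 with an estimated correlation), of thalamus higher in 12 of 13 (0.30, adjusted p = 0.878 with an estimated correlation) and of blood higher in all 6 (0.46, adjusted p = 0.277 with an estimated correlation). Other lists with a camera call had no member that passed over all genes. Interferon response genes lay higher in 24 of 27 cases (median 0.20) and reactive astrocyte genes in 16 of 18 (0.21). Complement genes lay higher in 9 of 13 (0.16), and each list had an adjusted p = 0.626 with an estimated correlation. Plaque-associated microglia genes lay at 0.07, cholesterol synthesis genes at -0.14 and cortex markers at -0.20 (each adjusted p = 0.878 with an estimated correlation).

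Within single backgrounds, Csf1r-Cre changed 9 genes at 4 months, 13 at 12 months, 11 in 5xFAD at 4 months and 11 in 5xFAD at 12 months, and 7 genes passed in all 4, always in the same direction. These were Atp6v0c, Atp6v0c-ps2, Rps2-ps10, Rps2-ps13, Hmga1b, Gm9825 and Gm14292. Apart from Atp6v0c and Hmga1b, the table annotates these as processed pseudogenes. The last 2 are predicted models outside the naming rule and were named after their values were seen. A fit on the compared groups alone called 4, 4, 6 and 12 genes, and 2 of the 7 in all 4, Atp6v0c-ps2 and Rps2-ps10. Median-of-ratios scaling called 5 of the 7 in all 4, without Atp6v0c and Rps2-ps13, the replicate block 5, without Hmga1b and Rps2-ps13, and a pseudocount of 1 called 6, without Rps2-ps13. At 4 months Rps2-ps13 did not pass without control replicate 4 (adjusted p = 0.0637), 6 (0.0502) or 8 (0.0807), or without Csf1r-Cre replicate 1 (0.19), 2 (0.172) or 5 (0.132). No member of any list passed over all genes in these comparisons except Trac at 12 months, at 2.63 ± 1.05 TPM (SD, n = 7) against 0.375 ± 0.392 TPM (SD, n = 3), whose adjusted p went from 0.0473 to 0.789 without the 2 libraries that stand apart, and to 0.0724 or more without any 1 of control replicates 1 and 2 and Csf1r-Cre replicates 1, 4, 5, 6 and 7. Coa4, Coprs and Gdf7 also passed at 12 months and had adjusted p of 0.572, 1 and 0.572 in that fit, and Coprs had 0.127 with median-of-ratios scaling. Without control replicate 2 alone these were 0.58, 1 and 0.378, and Coprs had 0.106 without control replicate 1 and 0.0823 and 0.0794 without Csf1r-Cre replicates 4 and 7. Beside the 12-month genes, markers of striatum lay lower in all 14 cases, at a median log2 fold change of -1.41, and markers of thalamus lay higher in all 13 (median 0.94), of blood in all 6 (median 0.89) and of choroid plexus in 12 of 14 (median 1.12). Lower too were excitatory neuron markers in all 13 cases (median -0.79), synapse genes in all 25 (-0.57), cortex markers in 12 of 13 (-0.54) and immediate early genes in 20 of 22 (-0.71). All 8 lists had a camera call, and each had an adjusted p = 0.965 with an estimated correlation. Without the 2 libraries that stand apart the camera adjusted p was 4.9e-09 for thalamus, 0.000472 for excitatory neurons, 0.00818 for immediate early genes, 0.169 for striatum, 0.604 for cortex, 0.693 for blood, 0.949 for synapse and 0.988 for choroid plexus. In 5xFAD at 12 months plaque-associated microglia genes lay at a median log2 difference of 0.34 (adjusted p = 0.676 with an estimated correlation), complement genes at 0.44 and reactive astrocyte genes at 0.56 (both adjusted p = 0.395 with an estimated correlation), beside striatum markers at -0.88 (adjusted p = 0.688 with an estimated correlation). In 5xFAD at 4 months markers of blood lay at 0.89 and of dentate granule cells at 0.81 (both adjusted p = 0.214 with an estimated correlation), and at 4 months without 5xFAD immediate early genes lay at -0.58 (adjusted p = 0.973 with an estimated correlation). The 12-month count was 28 without control replicate 1, 8 without control replicate 2 and 114 without control replicate 3, and in 5xFAD at 12 months it was 19 without 5xFAD Csf1r-Cre replicate 3. The median of all genes moved by -0.12 at 4 months and -0.14 at 12 months without 5xFAD. In the 12-month 5xFAD libraries, whose labels disagree on Csf1r-Cre, Atp6v0c-ps2 was 21.3 ± 17.2 TPM (SD, n = 7) and Rps2-ps10 2.27 ± 0.677 TPM, against 439 ± 40.3 TPM and 342 ± 99.2 TPM in 12-month 5xFAD libraries with Csf1r-Cre (SD, n = 5).

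**Figure D4:**
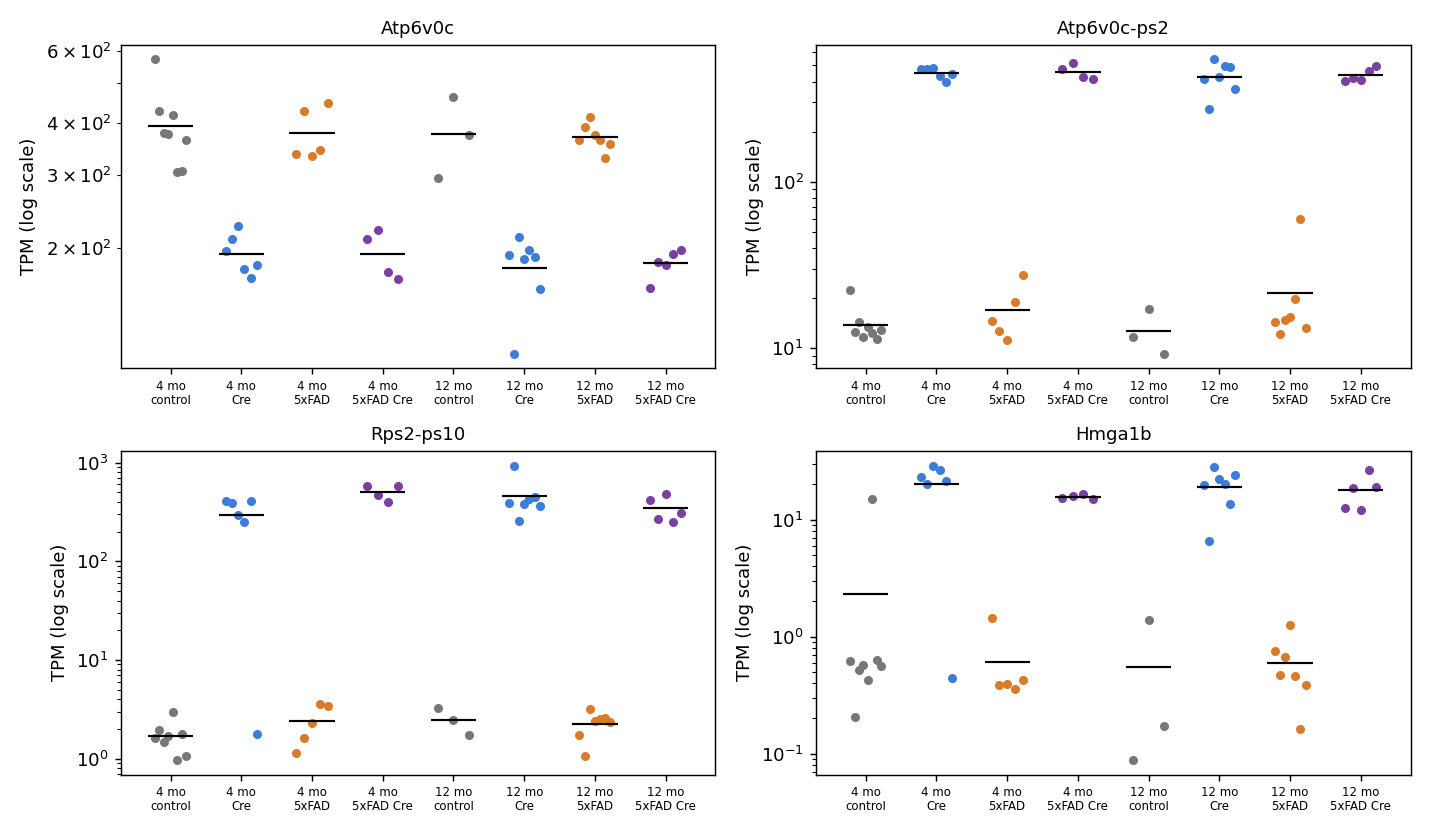
Atp6v0c, its pseudogene Atp6v0c-ps2, Rps2-ps10 and Hmga1b in each library, in TPM on a log axis, by group; points are libraries and lines are means. Atp6v0c-ps2 lies between 275 and 544 TPM in the 22 Csf1r-Cre libraries and between 9.24 and 59.9 TPM in the 23 others.

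No gene's response to 5xFAD differed with Csf1r-Cre at a limma adjusted p under the threshold. At 4 months 0 genes passed in limma and 0 under each alternative run. An unadjusted p under 0.05 was reached by 393 in limma, fewer than the 5% of genes that chance gives. At 12 months 0 passed in limma and 2156 had an unadjusted p under 0.05. At 12 months 1 gene passed with median-of-ratios scaling, 1 with no filter, 2 with a pseudocount of 1 and 4 with sample weights. The smallest adjusted p was 0.0985, for Gdf7, Gm42608 and Coprs, followed by Cd72 and Coa4 at 0.134. The difference in the 5xFAD effect on Apoe was 0.06 ± 0.305 (SE) at 4 months and 0.03 ± 0.32 (SE) at 12 months. The median of all genes differed by 0.14 at 4 months and 0.21 at 12 months. Among lists, homeostatic microglia genes had a median difference of 0.66 at 12 months (adjusted p = 0.954 with an estimated correlation) and excitatory neuron markers of 1.24 (adjusted p = 0.942 with an estimated correlation), beside choroid plexus markers at -1.84 (adjusted p = 0.954 with an estimated correlation) and thalamus markers at -1.22 (adjusted p = 0.942 with an estimated correlation). Immediate early genes lay at 1.35 at 12 months (adjusted p = 0.942 with an estimated correlation) and 0.92 at 4 months (adjusted p = 0.831 with an estimated correlation), where dentate granule markers lay at 1.31 (adjusted p = 0.391 with an estimated correlation) and striatum markers at -0.65 (adjusted p = 0.831 with an estimated correlation). The 12-month count was 33 without control replicate 3, 5 without 5xFAD Csf1r-Cre replicate 3, 1 without control replicate 1 and 1 without 5xFAD replicate 7.

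Age without 5xFAD moved 2 genes, both higher at 12 months. They were AC149090.1 (log2 fold change 1.27 ± 0.22, SE, adjusted p = 0.0222), which lies on an unplaced contig, and A530053G22Rik (log2 fold change 0.73 ± 0.14, SE, adjusted p = 0.0392), which is outside the naming rule and was named after its values were seen. Apoe differed by -0.10 ± 0.155 (SE, adjusted p = 0.834). Of the 13 thalamus markers 0 passed over all genes in limma and 5 were lower when adjusted over the list alone (adjusted p = 0.998 with an estimated correlation). Beside these, synapse genes lay lower in 24 of 25 cases (median -0.47), and markers of striatum lay higher in all 14 (0.48), mitochondrial transcripts in 12 of 15 (0.20) and complement genes in 10 of 13 (0.27). Homeostatic microglia genes lay higher in 14 of 18 cases (0.13) and plaque-associated microglia genes in 23 of 35 (0.08). Each of these lists had a camera call and an adjusted p = 0.998 with an estimated correlation. The camera adjusted p of striatum was 0.0767 with median-of-ratios scaling and 0.663 without the 2 libraries that stand apart. In the limma model 1868 genes had an unadjusted p under 0.05, and the count of called genes ranged from 0 to 4 when 1 library was left out.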

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

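The tests of the scale of TPM, of the 2 libraries that stand apart and of fewer control libraries were chosen after the results they bear on were seen. In 7 of the 63 sets of 4 to 8 libraries tested, for 9 genes, 1 library lay far from the others, where chance gives about 1 in 20. Apoe was 5434 TPM in 4-month Csf1r-Cre replicate 4 and 2392 to 3285 TPM in the others. Rps2-ps10 was 931 TPM in 12-month Csf1r-Cre replicate 2 and 253 to 449 TPM in the others. Cst7 was 20.2 TPM in 4-month 5xFAD replicate 4 and 2.13 to 6.86 TPM in the others. Gfap was 2281 TPM in 12-month 5xFAD replicate 6 against 703 to 1371 TPM, and Atp6v0c-ps2 was 59.9 TPM in that library against 12.1 to 19.6 TPM. In 4-month control replicate 1, Atp6v0c was 572 TPM against 306 to 428 TPM and Atp6v0c-ps2 was 22.4 TPM against 11.3 to 14.2 TPM.

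The 5xFAD effect differed between ages for 802 genes. None of the other 99 of 100 splits of the ages within genotype gave as many, and the highest gave 66, so chance is unlikely.

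With 5xFAD at 12 months in Csf1r-Cre carriers, genes that rose outnumber those that fell. Of the 2 libraries that stand apart, 12-month Csf1r-Cre replicate 2 alone belongs to the groups compared. The excess was not due to that library, since 93.7% of called genes rose without both. Whether a shift of the whole scale of TPM between libraries accounts for part of it stays open: 64.7% rose with median-of-ratios scaling, but this scaling centres the fold changes and so evens the balance whatever the cause. Such a shift does not account for the rise of plaque-associated microglia genes, since 27 of the 30 that were called, 90%, were called with that scaling too, a share that lies on the bound set for it after the result was seen. The real groups gave 1124 genes and the highest other split 5739. Of 100 splits, the real one included, 2 gave as many. The count makes chance less likely but does not exclude it, and the large split points to a structure of the samples. Of the genes that rose, 232 also rose without Csf1r-Cre in other libraries, where independent lists would share 17.3. This argues against chance for those 232, though genes that vary together make that expectation too low.

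The count of genes changed by 5xFAD at 12 months fell to 80 without control replicate 2. Fewer control libraries as such do not explain it, since the counts without another control were at least 345. A lower level of plaque-associated microglia genes in that library stays open: relative to all genes they lay -0.258 from the other 2 controls, with a 95% bootstrap interval of -0.421 to -0.061 over 35 genes that vary together, so that it is too narrow, and the bound of -0.5 set beforehand was wrong in counting a smaller fall as none. A difference in the tissue taken stays open too, since Ttr, a choroid plexus transcript, was 107, 8.87 and 6772 TPM in control replicates 1, 2 and 3. Control replicate 2 also had 16238 genes above 0, the fewest of all 45 libraries, against 20314 and 20593 in control replicates 1 and 3. Genes at 0 in that library lower the control mean, and their part in the count was not tested. The real groups gave 330 genes and the highest of the other 99 splits 156, so chance is unlikely.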

How the results depend on the processing

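The alternatives without the 2 libraries that stand apart were chosen after the data were seen. The Csf1r-Cre count over all backgrounds and the 0 genes of the interaction at 4 months stayed within 1.5 times of their value under every alternative run, and Xist level as a covariate moved no count beyond that. The cause was not tested for the changes that follow. Fitting only the compared groups called 0 genes for 5xFAD at 4 months, 172 at 12 months, 7 and 275 with Csf1r-Cre, 4, 4 and 6 for Csf1r-Cre at 4 months, at 12 months and in 5xFAD at 4 months, and 0 with age. Sample weights gave 525 for 5xFAD at 12 months, 12 and 3174 with Csf1r-Cre at 4 and 12 months, 14, 37 and 24 for Csf1r-Cre at 4 months, at 12 months and in 5xFAD at 12 months, 4 for the interaction at 12 months, 3271 for 5xFAD by age and 73 with age. Median-of-ratios scaling gave 5 and 3 for 5xFAD at 4 months without and with Csf1r-Cre, 1 for the interaction at 12 months, 475 for 5xFAD by age and 4 with age. No filter gave 2 for 5xFAD with Csf1r-Cre at 4 months, 20 and 21 for Csf1r-Cre at 12 months without and with 5xFAD, 1 for the interaction at 12 months and 492 for 5xFAD by age. A pseudocount of 0.1 gave 22 for Csf1r-Cre at 12 months and 1 with age, and a pseudocount of 1 gave 2 for the interaction at 12 months. Without the 12-month 5xFAD samples 0 genes changed with age; this alternative was not run where a comparison needs those samples.

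Without the 2 libraries that stand apart the counts were 129 for 5xFAD at 12 months, 8 for Csf1r-Cre at 12 months, 1543 for 5xFAD by age and 7 with age, and with median-of-ratios scaling as well 9, 79 and 9 for 5xFAD at 4 months, at 12 months and at 4 months with Csf1r-Cre, 7 for Csf1r-Cre at 12 months and 8 with age. With each library left out in turn, counts ran from 2 to 7 for 5xFAD at 4 months, 80 to 575 at 12 months, 0 to 5 and 532 to 3019 with Csf1r-Cre, 8 to 114 and 9 to 19 for Csf1r-Cre at 12 months without and with 5xFAD, 0 to 33 for the interaction at 12 months, 448 to 1627 for 5xFAD by age, and 0 to 4 with age.

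The log2 difference in Apoe, between -0.018 and 0.046 on deposited TPM, changed sign with median-of-ratios scaling, to 0.14 at 4 months, 0.27 at 12 months, -0.0040 in 5xFAD at 4 months and -0.065 in 5xFAD at 12 months; without 5xFAD the mean TPM already lay in the direction of the scaled value. It ranged over left-out libraries from -0.171 to 0.066, -0.079 to 0.201, -0.080 to 0.152 and -0.056 to 0.079; none passed the test. Of the 162 gene list calls over all comparisons at the preset correlation, 14 held with an estimated correlation, all upward.

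Replicate numbers did not pair the samples: 23 of 54 same-numbered pairs of an age correlated above 0.1 (42.6%), against 111 of 316 pairs with different numbers (35.1%), and 9 of 43 samples correlated best with a sample of their own number, where 6.53 would by chance. With the replicate block, limma called 159 genes for 5xFAD at 12 months, 7 for Csf1r-Cre in 5xFAD at 4 months, 212 for 5xFAD by age and 1 with age, and the Apoe difference at 4 months was 0.031.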

Other observations

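The tests of chromosome 17, of floxed Apoe and of genes called in comparisons that share no library were chosen after the result was seen. T cell transcripts rose with 5xFAD in Csf1r-Cre carriers at 12 months, in 3 of 9 genes over all genes tested and 4 when adjusted over the list alone (adjusted p = 0.152 with an estimated correlation). Ccl5, a chemokine of cytotoxic T cells, was 3.58 ± 0.662 TPM (SD, n = 5) against 0.698 ± 0.541 TPM (SD, n = 7), a log2 fold change of 1.89 (limma adjusted p = 0.00056), and Ms4a4b was 0.831 ± 0.326 TPM against 0.0927 ± 0.151 TPM, or 0.0435 TPM without Csf1r-Cre replicate 1 (limma adjusted p = 2.86e-05). Lcn2, a lipocalin of reactive astrocytes and of neutrophils that both lists hold, was 133 TPM in 5xFAD Csf1r-Cre replicate 2 and 2.21 to 18.1 TPM in the other 4, against 0 to 2.09 TPM in the 7 libraries without 5xFAD (limma adjusted p = 8.75e-06, and 8.28e-05 with a mean of 7.68 TPM without that replicate). It was the only 1 of the 8 measured neutrophil markers to pass.

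A hypothesis for the genes changed by Csf1r-Cre is a strain haplotype on chromosome 17 that travels with the transgene: 12 of the 26 genes, 46.2%, lie there, against 4.7% of all genes tested (Fisher's exact test, p = 5.67e-10), between 8236043 and 65438697. Reads that carry other alleles of Atp6v0c, Rps2 and Hmga1, all on that chromosome, might then be counted on their copies elsewhere; besides Atp6v0c, Rps2 differed by -0.35 (unadjusted p = 0.00333) and Hmga1 by -0.38 (unadjusted p = 0.00961), but neither passed over all genes (limma adjusted p = 0.962 and 0.975), so the bound set beforehand was not reached. Single libraries part these signals: 4-month Csf1r-Cre replicate 6 had 445 TPM of Atp6v0c-ps2 but 1.76 TPM of Rps2-ps10 and 0.442 TPM of Hmga1b, and 4-month control replicate 6 had 15.0 TPM of Hmga1b with 0.971 TPM of Rps2-ps10. Loss of Apoe from cells that express Csf1r cannot be told apart from the transgene and what travels with it, since 0 samples had Csf1r-Cre and no floxed Apoe. For the Csf1r-Cre genes over all backgrounds 4 of 100 splits, the real one included, gave as many as the real 26. The highest other gave 4812. The count makes chance less likely but does not exclude it, and such a split points to a structure of the samples. For the 7 genes that passed in all 4 single backgrounds, which share no library, chance is unlikely, and it stays open for the rest.

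Other splits of the same samples, 100 for each comparison with the real one, bear on the remaining counts. The shares of splits were not adjusted over the 13 comparisons. For 5xFAD at 4 months 3 splits, the real one included, gave as many as the real 2 genes, and the highest other gave 3. This makes chance less likely but does not exclude it. With Csf1r-Cre 10 splits gave as many, with 1 real gene and 4 as the highest other, so the count alone does not exclude chance. That gene, Ccl6, is 1 of the 2 called without Csf1r-Cre in other libraries, and none of the other 99 splits called either, so for Ccl6 chance is unlikely. For Csf1r-Cre chance is unlikely at 4 months (1 split, 9 real, 6 the highest other), in 5xFAD at 4 months (1 split, 11 real, 3 the highest other) and in 5xFAD at 12 months (1 split, 11 real, 6 the highest other). At 12 months 21 splits gave as many as the real 13 and the highest other gave 5312, so the count alone does not exclude it. Yet the 13 hold all 7 genes called in each of the 3 other backgrounds, which share no library with them. None of the other 99 splits called more than 4 of these 7, so chance is unlikely for the 7 and stays open for the rest. Of the 21 splits, 18 called at least 100 genes, and all 18 moved 12-month Csf1r-Cre replicate 2 into the other group, which points to that library as a structure of the samples. The interactions of 5xFAD with Csf1r-Cre had 0 real genes, so all 100 splits gave as many at each age, with 983 and 2180 as the highest others, which point to a structure of the samples too. With age 10 splits gave as many as the real 2, with 8 as the highest other, so chance cannot be excluded. For 5xFAD by age and at 12 months without Csf1r-Cre, 1 split each, the real one, gave as many, and with Csf1r-Cre 2 did.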
